A study of Homo sapiens with 6 samples.

How the data were processed

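RNA was sequenced from 6 libraries of the gastric cancer line MKN45, 2 each of control cells, KLF4 knockout cells and cells given losartan for 24 hours. Libraries were made with the NEBNext Ultra II kit from total RNA, per the labels' protocols. HISAT2 2.0.5, bcl2fastq and the genome build GRCh38 (hg38) are named per the submitters' processing notes. The read counter, the tool behind the FPKM values, the annotation release, strand handling and any filters are not given in the sources used here. The authors deposited a table of raw read counts per gene, with 1 column per library and no scaling. They also deposited a table of FPKM values. For the median gene of a library, the values themselves show the authors' count divided by gene length and by a library size. That size was 0.954 to 1.08 times the column total. How that library size was set is not given in the sources used here. Relative to the column total it rose with the TMM factors used here, from 0.954 in losartan replicate 2 (factor 0.910) to 1.08 in knockout replicate 1 (factor 1.05). Tests on FPKM values are therefore no independent check of that scaling. All 58735 gene identifiers and coordinates of the count table are identical to those of GENCODE release 29, and that annotation supplied transcript sequences for GC content. Every row named a gene, and no column of per-sample values was left without a sample.

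Groups were taken from the labels, and columns were matched to samples by name. Total counts ran from 19217655 to 55042085 per library, so the deepest library held 2.86 times the counts of the shallowest, which was a knockout library. A count of 0 was given a floor of 3 counts, and such floors cover counting error only, because reads amplified without molecular identifiers are not independent molecules. Replicates of a group differed by 12.3 to 19.8 times the chi-square expected from sampling, so none was treated as a library deposited a second time. All samples share 1 sequencing date in the labels, so no batch term was fitted. Losartan and the knockout were not combined in any library, so an interaction could not be tested.

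The fit, the lists and their tests, and the rule for naming genes in this paragraph and the next 2 were fixed before the data were examined. Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes passed filterByExpr with a minimum count of 10, which left 18007. Libraries were scaled by TMM factors, and CPM values are counts over these scaled library sizes. All 6 libraries entered 1 quasi-likelihood fit (glmQLFit with robust estimation, glmQLFTest, two-sided) with a mean per group and 3 residual degrees of freedom, so that the groups share 1 estimate of the spread. The 3 comparisons were the knockout against control, losartan against control and the knockout against losartan. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, and genes with an adjusted p below 0.05 were called, with no minimum fold change. The SE of a log2 fold change was its size over the square root of the F statistic. The common biological coefficient of variation was 0.102.

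Gene lists were fixed from general knowledge of gastric epithelium, tight junctions, the renin-angiotensin system and KLF4, with older and newer symbols of a gene where an annotation may use either. Lists with at least 5 tested members were tested with limma 3.58.1 (voom values, camera with a preset correlation of 0.01, two-sided), adjusted over the lists of a comparison. Camera with an estimated correlation and fry were alternatives. With an estimated correlation, camera rests on the 3 residual degrees of freedom of the fit, so it had little power here. Counts adjusted over the list alone are printed beside the others where a list passed and for tight junctions. In the knockout against losartan they are printed for tight junctions only. Over all lists, the 2 adjustments differed by at most 2 higher and 2 lower members in the knockout, by 4 and 2 with losartan, and by 1 and 3 in the knockout against losartan. No list past camera's threshold had a median, a mean and a test of different sign. Some lists share members with each other, and a few markers of other cell types, such as LYZ, are also expressed in gastric epithelium.

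Named genes were chosen by a rule. KLF4 and AGTR1 were always named. For each comparison with control the rule took the 10 highest and the 10 lowest log2 fold changes among protein-coding genes that were called, averaged at least 100 counts and did not overlap in CPM between the groups. From each list it allowed up to 4 members with the smallest p, and fewer were often printed, some members being not reported here. For the knockout against losartan it took the 5 highest and 5 lowest. For genes called in both comparisons with control it took, for each pair of directions, the 5 with the largest smaller absolute log2 fold change. Every tested tight junction gene could be named. MUC5AC, CLDN18 and others enter under more than 1 part of the rule. AGT was named because its count was 0, POLRMT, TFAM, TFB2M and TEFM because a test in the closing section rests on them, and both choices lie outside the rule and were made after seeing the data. Stability was counted over all genes allowed, also a choice made after seeing the data. There were 19 alternatives without a minimum fold change, of which 3 were likewise chosen later. Under those that tested the gene, 134 of 150 called genes that the rule allows, tight junction genes included, kept their call in the knockout, 105 of 139 with losartan and 22 of 28 in the knockout against losartan. Most of these genes were chosen for large changes or small p in the same data, so the shares do not describe calls in general. Tight junction genes alone kept 10 of 20, 2 of 10 and 13 of 19 calls.

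Alternatives fixed in advance were DESeq2 1.42.0, RLE factors, library totals as the only scaling, no count filter, a filter of 1 CPM in 2 libraries, fits of only the groups compared, the replicate number as a block, and a minimum absolute log2 fold change of 1. Others were limma on log2(FPKM + 1) and log2(FPKM + 0.1), a filter of 1 FPKM in 2 libraries, and leaving out each of the 6 libraries in turn. Leaving out 1 library leaves its group with a lone library, which is then assumed to vary like the other groups. Offsets that remove the trend of each library with GC content, or with GC content and transcript length, and a fit without mitochondrial genes were chosen after seeing the data. For changes shared by both comparisons with control, 100 simulations of unchanged groups gave the values expected from shared controls alone, if no gene changes. In each, all 6 libraries, the controls included, were drawn from the means of the control libraries.

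The tests were tried on simulated counts with 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold, drawn from the means and library sizes of the data. In the simulated knockout comparison, which ran on 17211 genes, edgeR recovered 56.7% of genes changed 1.5-fold, 86.6% of those changed 2-fold and 100% of those changed 4-fold, and 11.0% of its calls were false. For losartan on 17193 genes it recovered 55.2%, 85.1% and 100%, with 8.57% false, and for the knockout against losartan on 17188 genes 59.7%, 89.6% and 98.5%, with 10.8% false. The false share was thus above the 5% that the threshold aims at, in 1 simulated draw per comparison. Far fewer genes changed in these simulations than were called in the data, so the false share there need not carry over. All changed genes averaged above 1 CPM in the control libraries, so recovery of weaker genes was not tried. Data were handled with the R package data.table (version 1.17.8), Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.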

Results

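Gene expression was measured by RNA sequencing in MKN45 cells, an epithelial line established from a human gastric adenocarcinoma. The 6 libraries form 3 groups of 2: untreated wild-type cells (control), cells labelled as a knockout of the gene for the transcription factor KLF4, and wild-type cells given losartan for 24 hours. Losartan is a blood pressure drug that blocks the angiotensin II type 1 receptor. The series concerns that receptor, the spread of gastric cancer and tight junctions, the seals between neighbouring epithelial cells. Total counts were 31080813 and 30780310 in the control libraries, 19217655 and 48279914 in the knockout libraries, and 35668607 and 55042085 in the losartan libraries. Of 58735 annotated genes, 18007 had enough counts to be tested. The first principal component held 60.5% of the variance and set the knockout libraries apart, and the second held 22.8% and set the control libraries apart. Replicates of a group differed by more than sampling noise, so each library was counted as its own replicate. The labels do not say that replicates were separate cultures, so all p-values measure only the spread between these libraries, which may be technical.

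The targeted gene was read first. KLF4 (ENSG00000136826; GRCh38 chromosome 9, 107484852 to 107490482, minus strand) stood at 172 ± 5.38 CPM (SD, n = 2) in the control libraries and at 85.8 ± 27.1 CPM (SD, n = 2) in the knockout libraries. That is 2.00-fold lower, with a log2 fold change of -0.997 ± 0.163 (SE) and an adjusted p of 3.8e-04 in edgeR's quasi-likelihood test. Both knockout libraries therefore still held KLF4 reads, 1343 and 5282 of them. The labels call the gene deleted but do not say which part, so reads from a remaining part of the transcript check the label only in part. In the losartan libraries KLF4 was at 78.0 ± 3.10 CPM (SD, n = 2), 2.21-fold below the control libraries (log2 fold change -1.14 ± 0.16, SE; edgeR adjusted p = 3.1e-04). AGTR1, the gene of the receptor that losartan blocks (ENSG00000144891; chromosome 3, 148697784 to 148743008), had 0 counts in all 6 libraries. A count of 0 allows up to 0.149 CPM in the shallowest library and 0.0599 CPM in the deepest one, for counting error only. AGT, which encodes the precursor of angiotensin II, also had 0 counts in all 6 libraries.

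**Figure D1:**
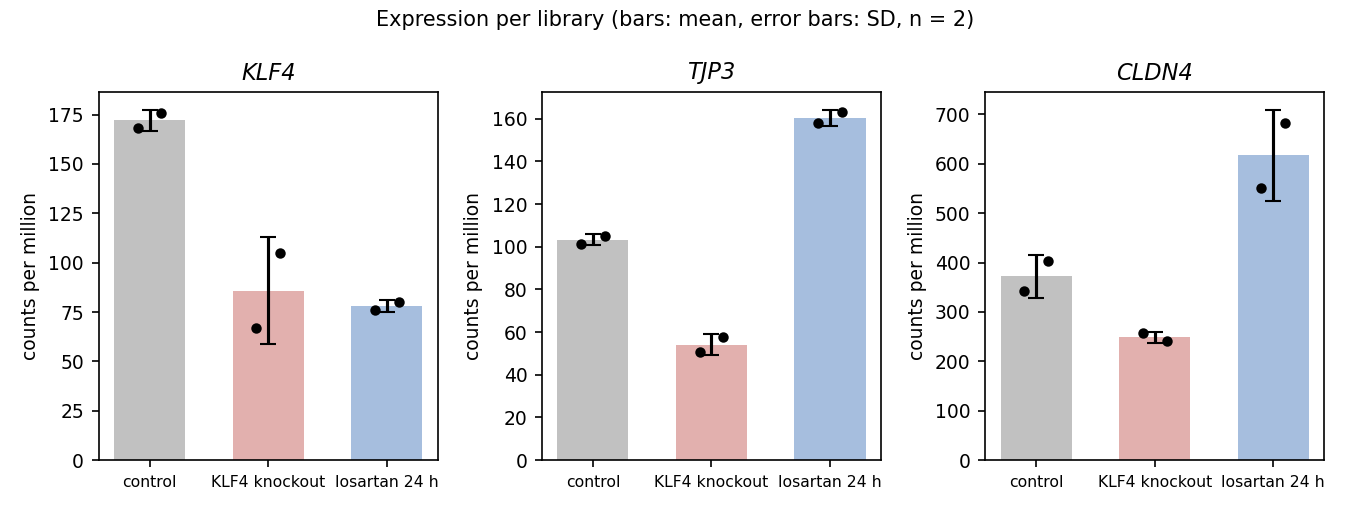
CPM (linear axes, TMM-scaled) of KLF4, TJP3 and CLDN4 in each library, by group; dots are libraries, bars are means of 2 and error bars are SD. KLF4 averaged 172 CPM in the control, 85.8 in the knockout and 78.0 in the losartan libraries.

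The libraries labelled KLF4 knockout were set against the control. As the control cells were untreated wild-type cells, an effect of making or selecting the knockout cells cannot be told apart from one of KLF4 loss. The labels do not say whether the knockout cells are a clone or a pool. MUC5AC, the gel-forming mucin of the stomach surface (ENSG00000215182; chromosome 11, 1157953 to 1201138), was 28.0-fold lower, at 10.8 ± 0.927 CPM against 300.5 ± 16.3 (SD, n = 2 each; log2 fold change -4.81 ± 0.15, SE; edgeR adjusted p = 2.1e-10). CLDN18, a claudin of gastric tight junctions (chromosome 3, 137998735 to 138033655), was 121-fold lower, with a log2 fold change of -6.92 ± 0.33. It averaged 0.0745 ± 0.0352 CPM in the knockout libraries, and MUCL3, given below, 0.0944 ± 0.0772 (SD, n = 2 each). Both means lie under the floor of 3 counts in knockout replicate 1 (0.149 CPM), so the size of both folds is uncertain. TNFRSF8, a receptor of the tumour necrosis factor family, had 0 counts in both knockout libraries against 127 to 155 in the control libraries. Set against a floor of 3 counts over the group, that is at least 106-fold lower. MUCL3, a mucin-like gene (-6.87 ± 0.41), CACNA1E, a calcium channel subunit (-6.41 ± 0.45), OTOF (-5.96 ± 0.28), CREB3L3 (-4.41 ± 0.33) and the glypican GPC3 (-4.39 ± 0.25) completed the lowest genes, together with REG4 (-4.85 ± 0.60) and CTSE, which encodes the gastric protease cathepsin E (-4.44 ± 0.61). The highest genes were led by CLGN, a chaperone of the endoplasmic reticulum (chromosome 4, 140388455 to 140427968), which was 21.4-fold higher (log2 fold change 4.42 ± 0.15; edgeR adjusted p = 4.8e-10). CELF2, an RNA-binding protein gene, was 11.8-fold higher, and FOSB, a subunit of the AP-1 transcription factor, was 10.9-fold higher (3.44 ± 0.43). The calcium channel gene TRPV6 rose 8.62-fold, BEX2 8.59-fold, FAM129A 7.92-fold, the growth factor gene FGF19 7.65-fold, PLEKHH2 6.66-fold, ZNF460 6.47-fold and PTPDC1 6.33-fold. Over all tested genes, 3967 were higher and 4071 lower in the knockout, of which 1109 and 1349 changed at least 2-fold. The calls for FOSB, REG4 and CTSE ended without control replicate 1 (edgeR adjusted p = 0.078, 0.065 and 0.074) and without control replicate 2 (0.061, 0.062 and 0.076), and the counts fell to 2313 higher and 2840 lower without control replicate 1 and to 2613 and 3017 without control replicate 2. The log2 fold changes of FOSB, REG4 and CTSE moved little, to 3.41, -4.88 and -4.58 without control replicate 1 and 3.44, -4.84 and -4.35 without replicate 2. Other folds depended more on 1 library. Without knockout replicate 2 the log2 fold change was -7.65 for CLDN18, -5.85 for MUCL3, -5.42 for CACNA1E, -7.17 for OTOF, -5.09 for CTSE and -3.77 for GPC3. Without knockout replicate 1 it was -7.68 for MUCL3 and -7.30 for CACNA1E.

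Fold changes in the knockout also followed the GC content of the genes, with a Spearman correlation of -0.485 across 11478 genes, which are not independent replicates. With the GC and length trend of each library removed, 5590 of the 8038 calls (69.5%) kept their direction and their side of the threshold, and 6 genes were called in the opposite direction. The gene list calls of this comparison given here were also made after that correction.

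Interferon-response genes fell together in the knockout. Of 38 tested members 34 were lower and 0 higher (34 and 1 adjusted over the list alone), with a median log2 fold change of -1.27. IFI27 fell 8.83-fold, PSMB9, a subunit of the immunoproteasome, 5.48-fold, OAS2, an antiviral RNA sensor, 4.73-fold and IFIT3 4.51-fold. Camera, which compares a list with all other genes, gave this list an adjusted p of 2.8e-20 (adjusted p = 0.41 with an estimated correlation). None of the 12 lists past the camera threshold in this comparison passed it with an estimated correlation.

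Both lineage lists passed camera's test downwards in the knockout. The intestinal list had 12 of 16 members lower and 0 higher, the same counts adjusted over the list alone (median log2 fold change -1.72; camera adjusted p = 8.8e-06, adjusted p = 0.55 with an estimated correlation). Among them were SPINK4 (18.3-fold lower), the goblet cell peptide gene TFF3 (5.67-fold) and LGR5, a stem cell receptor (4.95-fold). The gastric list had 9 of 18 members lower and 4 higher (10 and 4 adjusted over the list alone; camera adjusted p = 0.014, adjusted p = 0.62 with an estimated correlation, and 0.060 without knockout replicate 1). Its members went both ways: TFF1, a secreted peptide of surface mucous cells, was 4.62-fold lower and ANXA10 was 2.43-fold higher. Keratins and other epithelial differentiation genes had 19 of 31 members lower and 4 higher (20 and 4 adjusted over the list alone; median -0.83; camera adjusted p = 3.3e-05, adjusted p = 0.55 with an estimated correlation). KRT17 was 7.32-fold lower, the simple-epithelium keratin gene KRT8 2.65-fold lower and S100P 2.19-fold lower, while the splicing factor gene ESRP1 was 2.01-fold higher. In the list of targets linked to WNT signalling 13 of 20 were lower and 2 higher (14 and 2 adjusted over the list alone; camera adjusted p = 3.9e-04, adjusted p = 0.62 with an estimated correlation). MYC was 2.18-fold and TNFRSF19 3.04-fold lower.

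The cell cycle lists passed camera's test downwards in the knockout and the p53 list upwards. Of the S phase list 19 of 28 members were lower and 1 higher (21 and 1 adjusted over the list alone), and of the G2/M list 20 of 31 were lower and 0 higher (22 and 0 adjusted over the list alone). Median log2 fold changes were -0.44 and -0.49, and both lists had a camera adjusted p of 5.5e-07 (adjusted p = 0.62 and 0.65 with an estimated correlation). MCM5, part of the replicative helicase, was 2.88-fold lower, CDT1 2.38-fold, E2F1 2.07-fold, CDC20 2.34-fold, CCNB2 2.09-fold and PLK1 2.07-fold. The p53 list had 20 of 29 members higher and 1 lower (20 and 2 adjusted over the list alone; median 0.59; camera adjusted p = 5.4e-07, adjusted p = 0.41 with an estimated correlation). ZMAT3 was 3.50-fold higher, RRM2B 2.69-fold, RPS27L 2.21-fold and the cell cycle inhibitor gene CDKN1A 2.24-fold. Replication histone genes had 12 of 20 members higher and 1 lower (13 and 1 adjusted over the list alone; camera adjusted p = 2.7e-04, adjusted p = 0.62 with an estimated correlation), among them HIST1H2BC, 5.08-fold higher, and HIST1H2AC, 2.11-fold higher. Reads of these near-identical genes may be split between copies, so their values are uncertain.

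The stress list passed camera's test upwards in the knockout and the cholesterol list downwards. The stress and unfolded protein response list had 14 of 28 members higher and 2 lower (15 and 2 adjusted over the list alone; median 0.35; camera adjusted p = 4.5e-04, adjusted p = 0.55 with an estimated correlation). The 4 members with the smallest p, known for protein folding and degradation in the endoplasmic reticulum, were SEL1L (4.20-fold higher), HSPA5, the chaperone BiP (3.31-fold), DNAJB9 (3.09-fold) and HERPUD1 (2.11-fold). The cholesterol list had 18 of 28 members lower and 1 higher (18 and 2 adjusted over the list alone; median -0.49; camera adjusted p = 1.3e-04, adjusted p = 0.62 with an estimated correlation). DHCR7 was 2.27-fold and EBP 2.17-fold lower. Transcripts of the mitochondrial genome were 12 of 13 lower and 0 higher (13 and 0 adjusted over the list alone; median -2.33; camera adjusted p = 5.7e-12, adjusted p = 0.55 with an estimated correlation). MT-CO1 was 5.73-fold, MT-CO2 5.85-fold, MT-ND2 5.02-fold and MT-CYB 4.48-fold lower. All mitochondrial genes took 0.919% and 1.11% of the counts in the knockout libraries, against 5.56% and 4.00% in the control and 4.29% and 4.43% in the losartan libraries.

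Tight junction genes went both ways in the knockout. Of 35 tested members 12 were lower, 8 were higher and 15 did not pass, the same counts adjusted over the list alone. The list as a whole did not pass limma's camera test (median log2 fold change -0.21; camera adjusted p = 0.21), and its median was -0.048 with GC correction (adjusted p = 0.33). Besides CLDN18, the lower members included CLDN23 (-1.44 ± 0.26, SE), LSR, a protein of contacts between 3 cells (-1.12 ± 0.15), CLDN3 (-1.02 ± 0.13), TJP3, a scaffold protein (-0.93 ± 0.10), and PARD6B (-0.54 ± 0.11). MARVELD2, which encodes tricellulin (0.92 ± 0.11), OCLN, occludin (0.83 ± 0.12), PATJ (0.78 ± 0.12) and CLDN12 (0.75 ± 0.14) were higher. These 10 calls held under all alternatives in the counts and scaling that tested the gene, without a minimum fold change. The other 10 calls each ended under at least 1 of them. For these genes the first value is the log2 fold change over all 6 libraries, and p is that of the alternative. Fits without a library also have fewer degrees of freedom, so a call can end with its fold change hardly moved. That of CLDN2 was -3.73 without control replicate 1 and without control replicate 2, while that of JAM3 went to -0.72 without control replicate 1. The call of CLDN4 (-0.58) ended with GC correction alone, which brought it to -0.29 (edgeR adjusted p = 0.097), and that of CXADR went from 0.50 to 0.23 (adjusted p = 0.12). Leaving out control replicate 1 ended the calls of CLDN2 (-3.73; adjusted p = 0.089), JAM3 (-1.01; 0.15), TJP1 (0.38; 0.24), MPP5 (0.37; 0.23) and PARD3 (0.29; 0.14). Leaving out control replicate 2 ended those of CLDN2 (0.086), ILDR1 (-0.58; 0.14), CGN (-0.36; 0.12), CLDN6 (-1.94; 0.14), MPP5 (0.052) and PARD3 (0.25). Leaving out knockout replicate 1 ended TJP1 (0.087), MPP5 (0.18), CLDN6 (0.096) and PARD3 (0.18), and leaving out knockout replicate 2 ended JAM3 (0.095). GC correction also ended ILDR1, CGN, TJP1 and MPP5, with log2 fold changes of -0.36, -0.17, 0.21 and 0.083, and it ended CLDN6 at one about as large (-1.67; adjusted p = 0.075). DESeq2 ended PARD3 (adjusted p = 0.054), and limma on FPKM ended MPP5 and PARD3. The fold change of CLDN6, with 16 counts in knockout replicate 2 and 0 in replicate 1, was -1.35 without knockout replicate 1 and -7.78, a fitted value, without knockout replicate 2. That of CLDN3 went to -0.46 with GC correction and -0.42 with GC and length correction, and its call held. TJP1 and MPP5 changed sign once the GC and length trend was removed (log2 fold changes -0.0025 and -0.062).

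**Figure D2:**
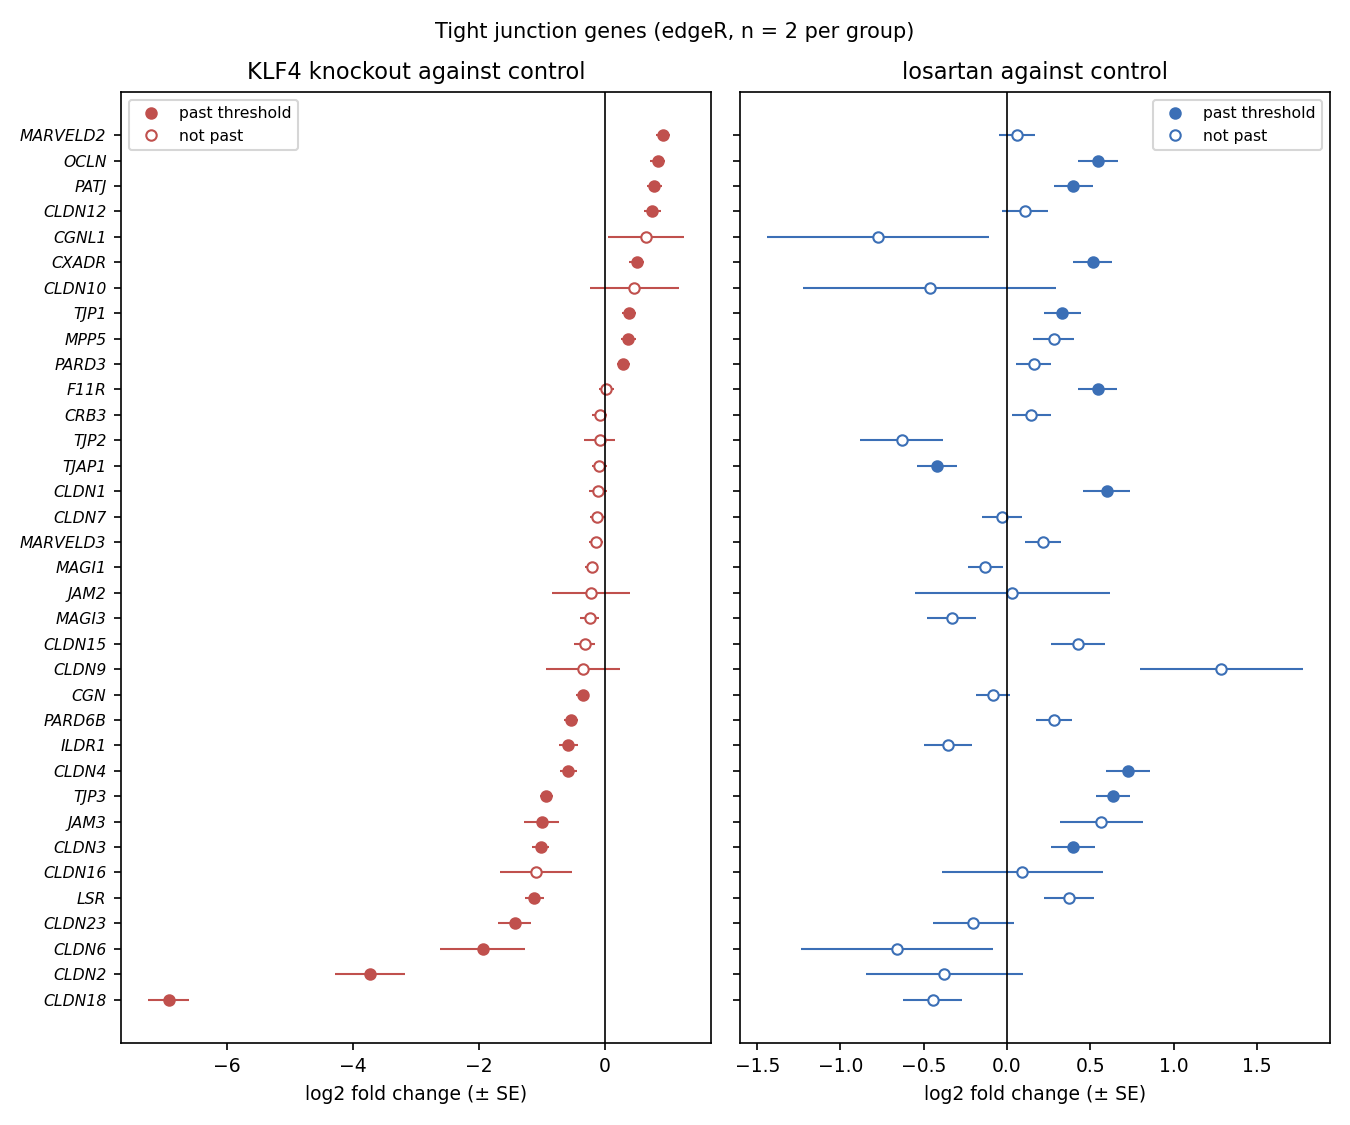
Log2 fold change with SE of the 35 tested tight junction genes against the control, for the knockout and for losartan (n = 2 libraries per group); filled points passed the edgeR threshold. In the knockout 12 were lower and 8 higher, and with losartan 1 was lower and 9 higher.

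The other lists did not pass camera's threshold in the knockout. Higher and lower members were 4 and 8 of 23 for adherens junctions and desmosomes, 4 and 6 of 21 for mesenchymal genes, 8 and 11 of 32 for integrins and proteases of invasion, and 2 and 7 of 13 for the renin-angiotensin list. For the TGF-beta list they were 6 and 10 of 25, for the KLF family 4 and 2 of 15, for genes linked to KLF4 1 and 4 of 15, and for PPAR targets 4 and 5 of 15. Hypoxia and glycolysis genes had 6 and 9 of 28, NF-kappaB genes 0 and 6 of 23, YAP targets 8 and 7 of 26, immediate early genes 7 and 11 of 26, and ribosomal protein genes 5 and 7 of 44. KLF6 (1.85-fold), KLF11 (1.89-fold) and KLF8 (1.95-fold) were the higher KLF members with the smallest p. Markers of other cell types were scarce. Fibroblast and immune lists had 3 tested members each and the endothelial list had 1. Higher and lower members were 1 and 2 for fibroblasts, 0 and 1 for immune cells and 0 and 0 for endothelium, too few for camera. LYZ fell 6.70-fold in the knockout, and it is a gene that gastric epithelium also expresses.

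Libraries of cells given losartan for 24 hours were compared with those of the control. As the control cells were untreated, an effect of solvent or handling cannot be told apart from one of the drug. Genes of cholesterol synthesis and uptake rose together. Of 28 tested members 26 were higher and 0 lower (27 and 0 adjusted over the list alone), with a median log2 fold change of 1.08. MSMO1 rose 3.65-fold, HMGCS1 3.34-fold, the feedback regulator INSIG1 3.29-fold and IDI1 3.23-fold. Camera gave this list an adjusted p of 1.6e-18 (adjusted p = 0.77 with an estimated correlation). Among single genes, SYT11, a vesicle protein gene (chromosome 1, 155859509 to 155885199), was higher, at 7.78 ± 3.61 CPM against 0.384 ± 0.00267 (SD, n = 2 each; log2 fold change 4.32 ± 0.38, SE; edgeR adjusted p = 4.2e-06). GALR2, a galanin receptor, was 13.6-fold and GAS7 12.8-fold higher. The glutamate transporter gene SLC1A3 (4.89-fold), FOSB (4.88-fold), SCEL (4.88-fold), IL3RA (4.54-fold), ZNF341 (4.16-fold), HSPA1L (4.12-fold) and EDN1, which encodes the vasoconstrictor endothelin-1 (4.04-fold), followed. The lowest genes were the potassium channel gene KCNK15 (chromosome 20, 44745780 to 44752313), 9.38-fold lower (log2 fold change -3.23 ± 0.14; edgeR adjusted p = 3.8e-08), NEK3 (8.52-fold), TCIM (8.40-fold), ELAC1 (8.23-fold), B3GNT6, a glycosyltransferase of mucins (7.72-fold), ZNF619 (7.21-fold), HEY1, a target of Notch (7.17-fold), IFT46 (7.05-fold), FAM167A (6.63-fold) and NDUFA4L2 (6.18-fold). In all, 2648 genes were higher and 2978 lower with losartan, of which 472 and 1004 changed at least 2-fold. Scaling by library totals alone shifted the median of all genes by -0.10 on the log2 scale and gave 1794 higher and 3914 lower genes. Without control replicate 1 the counts were 1154 and 1750, and without control replicate 2 they were 1323 and 1768. The FOSB call ended without control replicate 1 (edgeR adjusted p = 0.20), without control replicate 2 (0.17) and with library totals as the only scaling (0.053), and without losartan replicate 1 the log2 fold changes were 1.61 for FOSB and 3.00 for GAS7.

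The hypoxia and glycolysis list and the ribosomal protein list also passed camera's test upwards with losartan. The hypoxia list had 16 of 28 members higher and 0 lower (17 and 1 adjusted over the list alone; median 0.71; camera adjusted p = 4.8e-07, adjusted p = 0.79 with an estimated correlation). BNIP3L was 2.75-fold, BNIP3 2.15-fold, P4HA1 2.08-fold and the histone demethylase gene KDM3A 2.06-fold higher. NDUFA4L2, which is not in that list, was lower. Ribosomal protein genes had 21 of 44 members higher and 1 lower (24 and 1 adjusted over the list alone; median 0.35; camera adjusted p = 3.6e-07, adjusted p = 0.81 with an estimated correlation). RPL7A was 1.68-fold higher. Many processed pseudogenes copy these genes, so their counts are uncertain.

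The stress and unfolded protein response list passed camera's test downwards with losartan. Of its 28 members 17 were lower and 5 higher, the same counts adjusted over the list alone (median -0.61; camera adjusted p = 5.3e-05, adjusted p = 0.77 with an estimated correlation). TRIB3 was 4.98-fold lower, CHAC1 4.55-fold, the amino acid transporter gene SLC7A5 3.21-fold and DDIT4 2.25-fold. The gastric list had 10 of 18 members lower and 2 higher (12 and 2 adjusted over the list alone; median -0.60; camera adjusted p = 0.0013, adjusted p = 0.79 with an estimated correlation). TFF1 was 5.29-fold, SULT1C2 1.84-fold, ANXA10 1.63-fold and CAPN8 1.60-fold lower.

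Smaller list shifts followed with losartan. The p53 list had 12 of 29 members higher and 3 lower (14 and 3 adjusted over the list alone; camera adjusted p = 0.0053, adjusted p = 0.79 with an estimated correlation), with CCNG1 2.20-fold and BAX 1.73-fold higher and SESN2 1.86-fold lower. The NF-kappaB list had 7 of 23 higher and 0 lower, the same adjusted over the list alone (camera adjusted p = 0.0078, adjusted p = 0.81 with an estimated correlation), including the chemokine gene CCL5 (2.25-fold), TNFAIP2 (1.69-fold) and NFKB2 (1.61-fold). The TGF-beta list had 11 of 25 higher and 1 lower (12 and 2 adjusted over the list alone; camera adjusted p = 0.015, adjusted p = 0.81 with an estimated correlation), with TGFBR1 1.87-fold and PMEPA1 1.67-fold higher and BAMBI 2.14-fold lower. Its call ended without losartan replicate 2 (adjusted p = 0.23). The G2/M list had 8 of 31 higher and 0 lower (11 and 1 adjusted over the list alone; camera adjusted p = 0.016, adjusted p = 0.95 with an estimated correlation, and 0.065 with GC correction). Mesenchymal genes had 7 of 21 lower and 1 higher, the same adjusted over the list alone (median -0.52; camera adjusted p = 0.030, adjusted p = 0.81 with an estimated correlation). FOXC2 was 2.28-fold and AXL 2.47-fold lower, while S100A4 was 1.78-fold higher. That call ended without losartan replicate 1 (adjusted p = 0.057) and with GC correction (0.065). Keratins had 11 of 31 lower and 3 higher, the same adjusted over the list alone (camera adjusted p = 0.048, adjusted p = 0.84 with an estimated correlation), and the call ended without control replicate 1 (0.087), without losartan replicate 1 (0.21) and with GC correction (0.12). KRT17 was 2.34-fold and KRT7 1.62-fold lower.

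**Figure D3:**
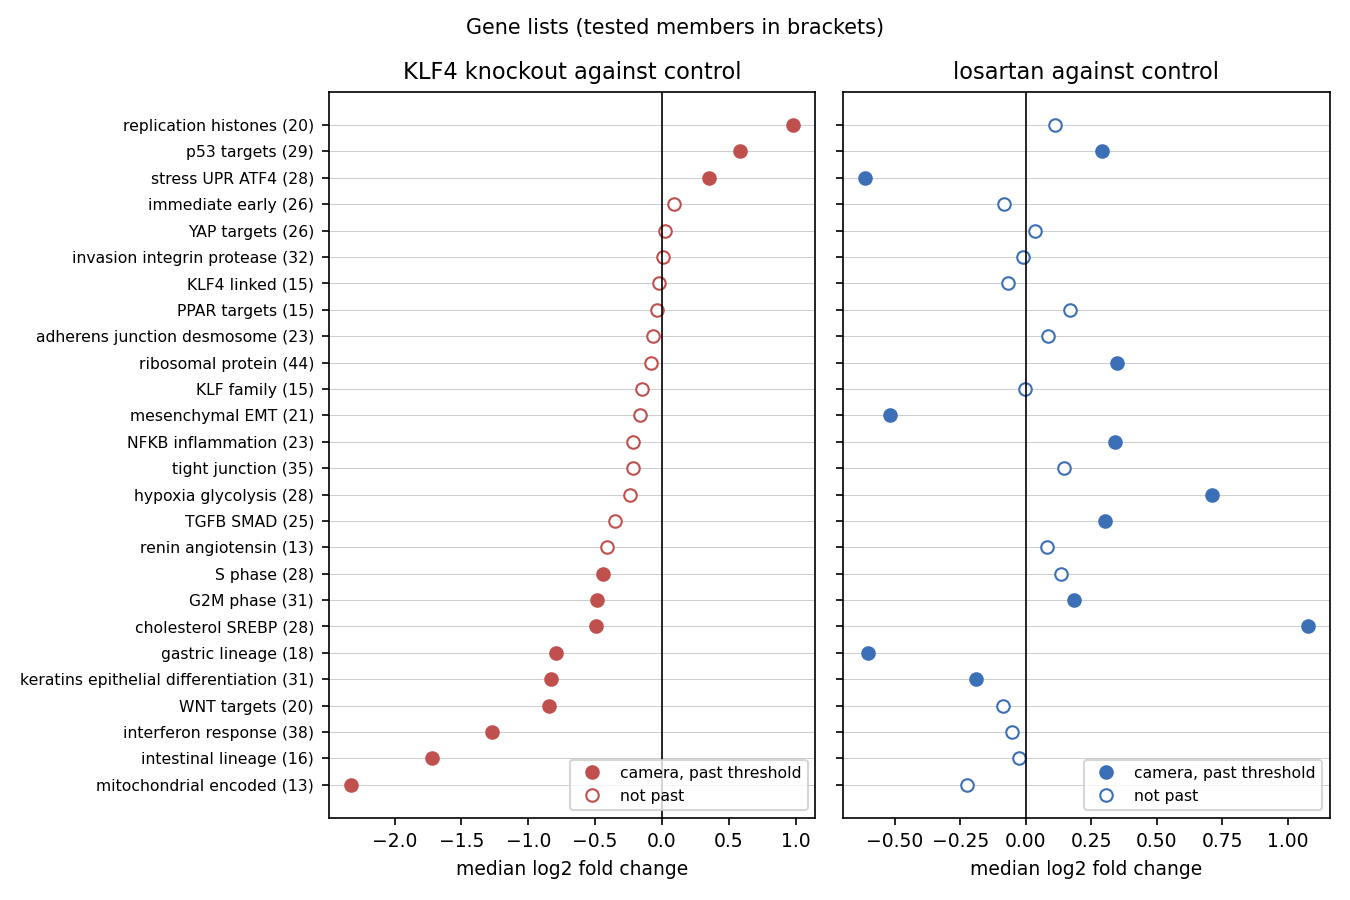
Median log2 fold change of each tested gene list against the control, for the knockout and for losartan. Filled points passed camera's threshold with the preset correlation. None did with an estimated one, a test with little power here. The interferon list stood at -1.27 in the knockout and the cholesterol list at 1.08 with losartan.

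Of 35 tight junction genes, 9 were higher with losartan, 1 was lower and 25 did not pass, the same counts adjusted over the list alone. The list as a whole did not pass (median log2 fold change 0.15; camera adjusted p = 0.081), though it did without control replicate 2 (adjusted p = 0.012) and without losartan replicate 1 (0.026). With library totals as the only scaling, which shifts all genes by -0.10, the median was 0.046 (adjusted p = 0.078). CLDN4 was 1.66-fold higher, at 617 CPM against 373 (log2 fold change 0.73 ± 0.13, SE; edgeR adjusted p = 0.0011), and TJP3 was 1.55-fold higher (0.64 ± 0.10; adjusted p = 4.6e-04). These were the 2 calls of the 10 that held under all alternatives without a minimum fold change. In what follows the first value of a gene is again its log2 fold change over all 6 libraries, and p is that of the alternative. Without control replicate 1 the calls ended for F11R (0.54; edgeR adjusted p = 0.071), OCLN (0.55; 0.092), CXADR (0.51; 0.053), CLDN1 (0.60; 0.055), PATJ (0.40; 0.17), CLDN3 (0.39; 0.22), TJP1 (0.33; 0.36) and the lower gene TJAP1 (-0.42; 0.10). Without control replicate 2 they ended for PATJ (0.059), CLDN3 (0.072), TJP1 (0.052) and TJAP1 (0.068). Without losartan replicate 2 they ended for CLDN1 (0.053), CLDN3 (0.14) and TJAP1 (0.12), and without losartan replicate 1 for TJP1 (0.10). Scaling by library totals ended the calls of PATJ (0.064), CLDN3 (0.070) and TJP1 (0.13), and limma on FPKM ended those of PATJ, CLDN3, TJP1 and TJAP1.

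Other lists did not pass camera's threshold with losartan. Higher and lower members were 2 and 1 of 23 for adherens junctions and desmosomes, 5 and 5 of 32 for integrins and proteases, 3 and 3 of 13 for the renin-angiotensin list, 2 and 3 of 15 for the KLF family and 2 and 2 of 15 for genes linked to KLF4. They were 2 and 4 of 16 for the intestinal list, 7 and 4 of 28 for S phase, 4 and 4 of 15 for PPAR targets, 4 and 5 of 38 for interferon genes and 7 and 7 of 26 for YAP targets. WNT targets had 6 and 5 of 20, immediate early genes 6 and 7 of 26, mitochondrially encoded genes 0 and 0 of 13, and replication histones 4 and 0 of 20. Adjusted over the list alone the histones had 0 and 0, and each of the 4 calls ended without control replicate 1 and without control replicate 2. Fibroblast markers had 1 higher and 0 lower, immune markers 2 and 0, and endothelial markers 0 and 0. LYZ was 1.86-fold higher.

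The knockout was also set directly against losartan, which tests whether the effects differ. Cholesterol genes were all lower in the knockout, 28 of 28 (median log2 fold change -1.48; camera adjusted p = 5.5e-16, adjusted p = 0.51 with an estimated correlation), and 33 of 38 interferon genes were lower and 1 higher (median -1.36; camera adjusted p = 1.5e-16, adjusted p = 0.51 with an estimated correlation). The stress list had 21 of 28 members higher and 1 lower (median 1.02; camera adjusted p = 1.2e-08, adjusted p = 0.51 with an estimated correlation). Tight junction genes had 15 of 35 members lower and 4 higher, the same counts adjusted over the list alone (median -0.26; camera adjusted p = 0.023, adjusted p = 0.54 with an estimated correlation). LSR (-1.49 ± 0.15, SE), TJP3 (-1.57 ± 0.11), CLDN3 (-1.41 ± 0.13), CLDN4 (-1.31 ± 0.13), PARD6B (-0.82 ± 0.11) and CLDN1 (-0.71 ± 0.14) were lower, and MARVELD2 (0.85 ± 0.11) and CLDN12 (0.65 ± 0.14) were higher. Of the 19 calls in this list 13 held under all alternatives without a minimum fold change that tested the gene, these 8 among them. The other 6 ended under at least 1, with p again that of the alternative. CLDN2 (-3.35) ended without control replicate 1 and without control replicate 2 (both 0.062), and was -2.63 without losartan replicate 2. CLDN9 (-1.64) ended with DESeq2 (0.090), without knockout replicate 1 (0.056) or 2 (0.073) and without losartan replicate 1 (0.089). MARVELD3 (-0.36) ended with library totals as the only scaling (0.15), without knockout replicate 1 (0.061) and without losartan replicate 2 (0.060). PATJ (0.38) ended without knockout replicate 1 (0.15), without losartan replicate 2 (0.052) and with GC and length correction, which brought it to 0.058 (0.60). TJAP1 (0.33) ended with DESeq2 (0.061), with only the 2 groups (0.059), with limma on FPKM, without knockout replicate 2 (0.30), without losartan replicate 2 (0.23) and without control replicate 1 (0.056) or 2 (0.057). CGN (-0.27) ended with library totals (0.34), with only the 2 groups (0.060), with GC correction (0.27) and without any 1 of the 6 libraries (0.057 to 0.10). CLGN (48.2-fold), FAM129A (43.1-fold), CELF2 (28.6-fold), KCNE4 (26.7-fold) and CFAP74 (23.6-fold) were the highest genes. TNFRSF8 was at least 117-fold lower, and MUCL3 (-7.17 ± 0.41), CLDN18 (-6.48 ± 0.33), CACNA1E (-6.27 ± 0.45) and SYT11 (-6.22 ± 0.47) were the other lowest. In the knockout libraries MUCL3, CLDN18 and SYT11 averaged 0.0944, 0.0745 and 0.114 CPM. These means lie under the floor of 3 counts in knockout replicate 1 (0.149 CPM), which leaves the size of those folds uncertain. Leaving out 1 library moved some of the highest and lowest genes. Without knockout replicate 2 the log2 fold change was -6.15 for MUCL3, -7.21 for CLDN18 and -5.29 for CACNA1E. Without knockout replicate 1 it was -7.98 for MUCL3 and -7.16 for CACNA1E, and without losartan replicate 2 it was 5.43 for CELF2. In all, 4895 genes were higher and 4745 lower in the knockout, and 6093 and 3617 with library totals as the only scaling, which shifted the median of all genes by 0.15 on the log2 scale. The remaining lists past camera's threshold are given with their lower and higher members. Lower in the knockout were mitochondrial transcripts (12 and 0 of 13), G2/M (26 and 1 of 31), S phase (25 and 1 of 28), hypoxia (19 and 2 of 28), ribosomal proteins (21 and 0 of 44), NF-kappaB (15 and 0 of 23), intestinal (11 and 1 of 16), TGF-beta (15 and 4 of 25) and keratins (15 and 4 of 31). Higher were p53 targets (4 and 17 of 29) and histones (0 and 9 of 20). All of these lists had a camera adjusted p of 0.54 to 0.70 with an estimated correlation. The histone call ended without knockout replicate 2 and the keratin call with GC correction (camera adjusted p = 0.14).

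Changes common to both comparisons with the control were counted next. In both, 785 genes were higher and 984 lower, against 583 and 673 for independent lists of the same lengths. Another 602 genes were higher in the knockout and lower with losartan, and 562 the reverse, against 656 and 599. B3GNT6 (5.54-fold and 7.72-fold), TFF1 (4.62-fold and 5.29-fold), OTOF (62.4-fold and 4.53-fold), the kinase gene SGK1 (9.05-fold and 4.12-fold) and SPRR1A (5.66-fold and 4.08-fold) were lower in the knockout and with losartan. FOSB (10.9-fold and 4.88-fold), the immediate early gene EGR1 (3.71-fold and 3.66-fold), NBEA (4.75-fold and 3.48-fold), CILP2 (3.14-fold and 3.38-fold) and IL3RA (2.68-fold and 4.54-fold) were higher in both. FAM129A, CFAP74, KCNE4, LHX9 and INHBE rose in the knockout (7.92-, 4.89-, 5.66-, 4.83- and 5.41-fold) and fell with losartan (5.45-, 4.82-, 4.72-, 4.56- and 3.74-fold). EDN1, ZBED2, TNNC1 and KRT15 went the other way, 3.99-, 4.14-, 3.35- and 2.96-fold lower in the knockout and 4.04-, 3.59-, 3.60- and 3.34-fold higher with losartan, as did SYT11 (log2 fold changes -1.90 ± 0.69 and 4.32 ± 0.38). The INHBE call with losartan ended without control replicate 1 (edgeR adjusted p = 0.083) and without control replicate 2 (0.066), and its log2 fold change was -2.51 without losartan replicate 1. The SYT11 call in the knockout ended without either control library (0.080 without replicate 1, 0.075 without replicate 2) and without either knockout library (0.084 and 0.35). It also ended in limma on FPKM (adjusted p = 0.76 with a pseudocount of 1), as did the CFAP74 call with losartan (0.057). The FOSB calls ended without either control library (0.078 and 0.061 in the knockout, 0.20 and 0.17 with losartan).

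Both comparisons use the same control libraries, which alone produces agreement. Across 12436 genes the log2 fold changes had a Pearson correlation of 0.080. Unchanged groups sharing 2 simulated control libraries averaged 0.50 in 100 simulations. All 6 libraries were drawn afresh from the control means, so other traits of the real control libraries did not enter. The share of genes with the same sign was 55.1%, against 66.7% simulated. Simulated groups shared 0.24 higher and 0.19 lower calls on average. No gene was changed in the simulations, whereas many were called here, so these simulated values are no benchmark for the data. The covariance of the log2 fold changes was 0.0276, above the simulated range (mean 0.0137, highest 0.0178). Log2 fold changes fell with GC content in both comparisons, by -0.33 in the knockout and -0.11 with losartan per 10 points of GC. The simulations held no such trend, so the higher covariance cannot be told apart from a trend with GC common to both. A split of the 2 control libraries would leave 1 for each comparison and was not run, so part of the overlap may come from them. Without control replicate 1 the overlaps were 197 higher and 468 lower in both, 245 higher in the knockout and lower with losartan, and 226 the reverse, and without control replicate 2 they were 337, 537, 224 and 215.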

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

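The GC, the GC and length, and the mitochondrial alternatives were chosen after seeing the data, and the others before. Counts of calls stayed within 1.5 times under every change of tool, scaling, filter, unit or offsets, apart from the following. A minimum absolute log2 fold change of 1 left 1109 higher and 1349 lower genes in the knockout, 472 and 1004 with losartan, and 2080 and 1781 in the knockout against losartan. With it, 79 genes were higher in both comparisons with control, 165 lower in both, 107 higher in the knockout and lower with losartan, and 53 the reverse. Fewer genes follow from that rule's construction. Leaving out 1 library at a time gave 2313 to 4216 higher genes in the knockout, and 1154 to 3008 higher and 1750 to 3167 lower genes with losartan. Overlaps then ran from 197 to 829 (higher in both), 468 to 1088 (lower in both), 224 to 548 (higher in the knockout, lower with losartan) and 215 to 601 (the reverse), lowest without control replicate 1 or 2. These fits hold fewer samples. DESeq2 called 3366 higher and 3643 lower genes in the knockout and 2480 and 2477 with losartan. Scaling by library totals moved the share of higher calls with losartan from 47.1% to 31.4%, and from 50.8% to 62.7% in the knockout against losartan.

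With an estimated correlation, a test with little power here, camera passed 0 lists in the knockout and 0 with losartan. It also passed 0 lists in the knockout against losartan, where the tight junction median of -0.26 had a camera adjusted p of 0.54. Fry, which does not compare a list with other genes, kept more of them. Of the lists past camera's threshold with the preset correlation, tight junctions aside, fry passed 10 of 12 in the knockout and 2 of 11 with losartan. In the knockout against losartan it passed 13 of 14, and also tight junctions (fry adjusted p = 0.023). The tight junction median with losartan was 0.046 with library totals as the only scaling and 0.15 to 0.23 with 1 library left out, and the list passed without control replicate 2 (adjusted p = 0.012) and without losartan replicate 1 (0.026). Of the genes named in the text, 90 of 104 kept their call or its absence in the knockout under all alternatives without a minimum fold change that tested them, 70 of 81 with losartan and 18 of 24 in the knockout against losartan. The filter of 1 FPKM, for example, tested 96, 77 and 21 of these genes. In the knockout TJP1 (-0.0025) and MPP5 (-0.062) reversed with GC and length correction. The cause of these changes in lists and genes was not tested. The replicate numbers do not pair the samples: deviations of libraries with the same number correlated at -0.036, 0.031 and -0.022. With the replicate block 3969 higher and 4137 lower genes were called in the knockout and 2667 and 3043 with losartan, the FOSB call with losartan ended (adjusted p = 0.088) and so did the keratin list (0.051) and CLDN2 in the knockout against losartan (0.054). Depth limits genes near the floor of 3 counts, which is 0.149 CPM in the shallowest library.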

Other observations

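The tests of GC and length bias on mitochondrial transcripts, of a GC bias common to both knockout libraries, of GC and length bias on chromosome 8, of a fall of the mitochondrial transcription machinery to 0.5 times the control level or less, and of low control values as the whole cause were chosen after the results were seen; the other tests were written before. Several genes passed the edgeR test singly in lists that did not pass as groups. In the knockout, KRT19, a simple-epithelium keratin gene, was 4.31-fold lower (log2 fold change -2.11 ± 0.14, SE), the envoplakin gene EVPL 2.82-fold lower, and F3, which encodes tissue factor, 6.04-fold lower (-2.60 ± 0.13). ID1, a target of BMP signalling, was 4.46-fold lower. The matrix protein gene TNC (2.66 ± 0.34) and the stromelysin gene MMP10 (2.87 ± 0.34) were 6.34-fold and 7.29-fold higher. With losartan, the YAP target AMOTL2 was 3.28-fold and the integrin gene ITGB8 2.29-fold higher, and the collagenase gene MMP1 was lower (-2.24 ± 0.35, and -2.88 without losartan replicate 2). FOS was higher in both, 1.93-fold in the knockout and 2.11-fold with losartan.

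Mitochondrially encoded transcripts had a median log2 fold change of -2.33 in the knockout, and both knockout libraries held fewer of them than any other library. Removing the GC and length trend left a median of -2.26, which argues against that trend as the whole cause. The 75 nuclear genes of the respiratory chain had a median of -0.30, with 34 lower and 2 higher and only 2 of them lower by 1 or more, which argues against a fall of the whole respiratory chain programme by the same amount. The lowest of the 4 genes of the mitochondrial transcription machinery was POLRMT, which was called lower (-0.37 ± 0.10; edgeR adjusted p = 0.010). TFB2M was called higher (0.42; adjusted p = 0.014), and TFAM (0.22) and TEFM (-0.11) were not called. The lowest value less 2 SE was -0.57, which argues against a fall of any of them to 0.5 times the control level or less. Whether the smaller fall of POLRMT plays a part stays open, as its value is within 2 SE of the bound of -0.5 set for it. An effect of the knockout, fewer mitochondrial genomes in the knockout cells, and RNA preparation may each account for the pattern, and these data hold no test of them.

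Fold changes in the knockout fell with GC content, by -0.33 on the log2 scale per 10 points of GC over 11478 genes, against -0.11 with losartan. A GC bias that varies from library to library had its steepest slope between the 2 knockout replicates (-0.17), 0.502 times the slope against control. That ratio is only just over the bound of 0.5 set for it, and the control (0.050) and losartan (-0.050) pairs were far below it. A bias common to both knockout libraries was also open: the slope against losartan was -0.22, as such a bias or an effect of the knockout would both give. Part of the trend may therefore be technical, and a change of transcripts by the knockout was not tested apart from it.

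The 136 genes tested on the short arm of chromosome 8 (GRCh38, 406428 to 43202855) were picked from windows over all chromosomes, with a region of chromosome 12 seen and not followed up. Their median log2 fold change in the knockout was 0.33 ± 0.06 (SE), above 99.76% of 8255 runs of as many neighbouring genes, and 71.3% of the genes lay above 0. The SE of each median in this paragraph comes from the spread across the arm's genes. These are not independent replicates, so it measures no spread between libraries. Correction for GC and length lowered the median to 0.16 ± 0.04, still above all other runs (highest 0.11), so part of the rise went with the GC and length trend, technical or not, and that bias stays open. The median against losartan, where no control library enters, was 0.32 ± 0.06. By library, the medians less the control mean were 0.30 and 0.29 in the knockout and 0.020 and 0.055 with losartan. These values argue against low control values as the whole cause, though a small part stays open, as losartan against control gave 0.032 ± 0.042. Extra copies of the arm in the knockout cells are a candidate explanation that these data cannot decide. The corrected median against losartan was 0.22 ± 0.06, above all other runs and just over its bound of 0.2, with 65.4% of the genes above 0. Because the arm was picked for its values in these knockout libraries, that rank largely restates the choice. The same knockout libraries gave the pattern and the test, and a copy number change in a selected clone and another effect of the knockout were not tested apart, as no DNA data were used here.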
